A study of Mus musculus with 14 samples.

How the data were processed

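Liver RNA of 52-week-old wild-type and Abcb11 knockout mice was sequenced in 14 libraries of 5 groups, given by the sample labels: wild-type female (n = 2), knockout female non-tumour (n = 3), knockout female tumour (n = 3), wild-type male (n = 3) and knockout male (n = 3). Per the labels, the authors extracted total RNA, sequenced it in pairs of reads, aligned the reads to GRCm38 with HISAT2 2.0.5 and counted fragments per gene with featureCounts 1.5.0-p3. The count values, 1 column per library, were deposited by the authors as whole fragment counts without scaling. The FPKM values in the deposited table were scaled by the authors to gene length and to a library total that differs from the sum of the count column, and they were checked but not tested here. The strand setting of the counting is not stated, so genes that overlap another gene are uncertain, as are families of near-identical genes.

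The table holds 54532 genes, and 27 symbols that had turned into dates were repaired from their gene IDs. Library totals were 14745140 to 19480538 counts. Scaling (TMM), the low-count filter (filterByExpr on the 5 groups, leaving 17874 genes) and a quasi-likelihood F test with robust dispersion were run in edgeR 4.0.16 under R 4.3.3, in 1 fit of all 14 libraries without a covariate. The common biological coefficient of variation was 0.442. The 7 comparisons were non-tumour knockout against wild-type females, tumour against non-tumour, tumour against wild-type females, knockout against wild-type males, the difference of the knockout effect between the sexes (non-tumour females minus males), wild-type males against wild-type females, and knockout males against non-tumour knockout females. Tests were 2-sided and adjusted by Benjamini-Hochberg over all genes within a comparison, with a threshold of 0.05. Every adjusted p of a gene is from this edgeR test unless another tool is named. Floors and count ratio intervals cover counting error alone. The floor for a group without counts was 3 counts per library.

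The 38 gene lists, with 767 members together with 2 lists used as checks, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, once with a preset correlation between genes of 0.01 and once with an estimated correlation, and adjusted over the 38 lists within a comparison. Members past the threshold were counted adjusted over all genes and adjusted over the list alone. Of the list members 1 could not be matched to a gene ID. The genes named are Abcb11 and sex chromosome genes, for each comparison up to 8 rising and 8 falling protein-coding genes with the largest fold among those past the threshold (at least 5 CPM in the higher group and no overlap between libraries; 5 and 5 for the difference between the sexes), the 3 list members with the smallest p of each list described, and genes of bile acid synthesis, uptake and export. Some genes that meet this rule are not reported here. The groups, comparisons, tests, lists, rule for named genes and first set of alternatives were chosen before the data were examined.

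The alternatives were RLE and upper-quartile scaling, no low-count filter (28842 genes), a filter of 1 CPM in 3 libraries (15279 genes), DESeq2 1.42.0, limma-voom with quality weights, a fit of the compared groups alone, the replicate number as a block, and each library left out in turn. Added after seeing the data were a clock score as a covariate (the mean log2 CPM of 8 evening genes minus that of 4 morning genes), both libraries of female knockout number 1 left out, and the block with number 1 left out. The labels do not say whether equal numbers mark 1 animal. Over 8445 genes, centred within groups, tumour and non-tumour libraries of the same number had correlations of 0.489, 0.418 and 0.308. Each lay above those of the different numbers, so the block was read there as a possible pairing. Knockout males and non-tumour females, which cannot share an animal, reached 0.439 for number 3 and 0.405 for male 1 with female 2. Such values therefore do not show that equal numbers mark 1 animal. Knockout and wild-type males of the same number had −0.0323, −0.205 and −0.291, and in the other groups equal numbers did not lie highest throughout.

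The fit was tested on simulated data in 3 runs for 3 of the comparisons. Genes changed 4-fold were recovered in 49%, 55% and 54% of cases (non-tumour knockout against wild-type females, tumour against non-tumour, knockout against wild-type males) and genes changed 2-fold in 4.3%, 6.7% and 7.3%. False calls were 5.9%, 2.6% and 4.7% of calls, and lists passed by chance in 1, 1 and 0 of 114 cases with the preset correlation. The simulated genes were drawn independently of each other, without a clock phase or a library that stands apart. These rates therefore do not cover lists whose genes vary together, nor such features of the real libraries.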

Results

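The livers of 52-week-old C57BL/6J mice, a common inbred laboratory strain, were profiled by RNA sequencing in wild-type animals and in animals without a working Abcb11 gene. Abcb11 encodes the bile salt export pump, which moves bile salts from hepatocytes into the bile canaliculi. The 14 libraries fell into 5 groups: wild-type females (n = 2, numbered 2 and 3; the design text gives 3 mice per group, and a number 1 is not analysed here), non-tumour liver of knockout females (n = 3), tumour tissue of knockout females (n = 3), wild-type males (n = 3) and knockout males (n = 3). Total counts per library ran from 14745140 to 19480538, and 17874 of the 54532 genes in the table were tested. Levels are given as TMM-scaled CPM with the SD, and log2 fold changes with an SE. This SE is the size of the log2 fold change divided by the square root of edgeR's F statistic. It is therefore derived from the test and is no separate measure of error. Genes below are named for each comparison first by size of change and then by membership of gene lists.

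Abcb11 (ENSMUSG00000027048, chromosome 2, 69238282 to 69342616, GRCm38) was lower in every knockout library than in every wild-type library. Its level was 379 ± 154 CPM in wild-type females (n = 2), 25.0 ± 9.61 CPM in non-tumour knockout liver (n = 3) and 25.2 ± 8.34 CPM in tumours (n = 3). In males it was 309 ± 12.3 CPM in wild type and 80.7 ± 21.0 CPM in knockout liver (n = 3 each). The log2 fold change was −3.93 ± 0.38 between non-tumour knockout and wild-type females (edgeR adjusted p = 0.000273) and −1.94 ± 0.34 between knockout and wild-type males (edgeR adjusted p = 0.00127). The fall was larger in females than in males, by −1.99 ± 0.49 on the log2 scale (edgeR adjusted p = 0.0181 for the difference). Reads on the gene remained in every knockout library, with 355 counts in the lowest, and the labels do not state which part of the gene was deleted.

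**Figure D1:**
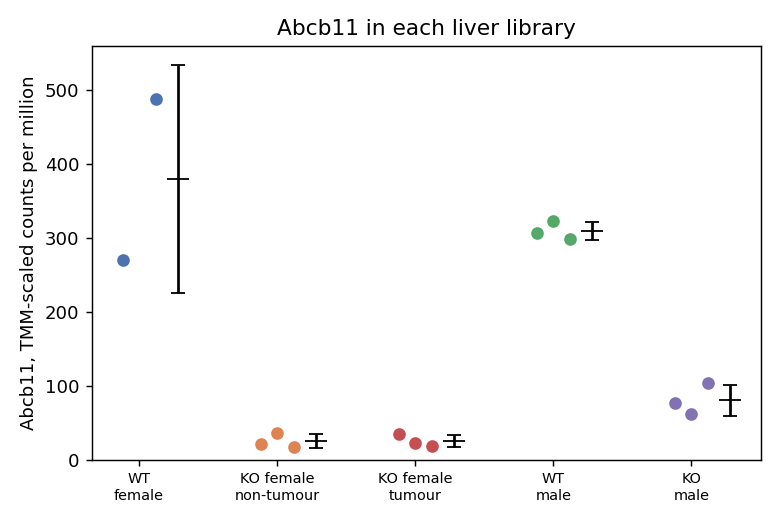
Abcb11 in TMM-scaled CPM (vertical axis) for each of the 14 libraries, by group; each point is 1 library, and the bar beside the points is the group mean ± SD. The wild-type libraries lie between 270 and 489 CPM and the knockout libraries between 17.9 and 104 CPM.

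The sex chromosome genes matched the labelled sexes. Xist, which is transcribed from the inactive X chromosome, stood at 2801 ± 211 CPM in wild-type females, 1388 ± 319 CPM in non-tumour knockout liver and 1210 ± 180 CPM in tumours, against 0 in wild-type males and 0.253 ± 0.0724 CPM in knockout males. The Y-linked gene Ddx3y had no counts in any female library and stood at 79.1 ± 24.3 CPM in wild-type and 52.3 ± 5.79 CPM in knockout males (n = 3 each).

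The first comparison asked how non-tumour liver of knockout females differed from wild-type female liver. Beside Abcb11, the sulfotransferase gene Sult2a8 (chromosome 7, 14410686 to 14446769) fell from 187 ± 46.3 to 1.97 ± 1.66 CPM, the cytochrome P450 gene Cyp3a16 from 135 ± 70.9 to 1.78 ± 0.427 CPM, and E2f8, a transcription factor of the cell cycle, from 26.3 ± 4.27 to 1.66 ± 1.36 CPM (n = 2 wild type, n = 3 knockout). The glutathione transferase gene Gstm3 went from 15.9 ± 8.93 to 678 ± 298 CPM (log2 fold change 5.41 ± 0.78, edgeR adjusted p = 0.00376) and Nqo1, a quinone reductase, from 4.77 ± 0.403 to 40.9 ± 22.4 CPM (3.10 ± 0.41, edgeR adjusted p = 0.00268).

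By size of change, Gsta1 (7.65 ± 1.64), Smpd3 (7.14 ± 1.14), Akr1b7 (6.71 ± 0.98), Tmprss4 (6.48 ± 1.03), Scn2a (6.13 ± 1.07) and Lrtm2 (5.68 ± 1.24) also rose. The glutathione peroxidase gene Gpx2 had no counts in wild-type females and was at least 8.23-fold higher in the lowest knockout library, over a floor of 3 counts per library. Such a limit is taken here and below from the lowest library of the higher group. Dnah1 had 3 counts in all in wild-type females, and its ratio had a counting interval of 27.7 to 397. Besides the genes above, the largest falls were those of Mup3 (−6.55 ± 1.42), Adrb3 (−5.27 ± 0.93), Sult5a1 (−3.41 ± 0.83) and Sdr9c7 (−3.37 ± 0.65). Cyp3a16 belongs to the list of female-biased liver genes, whose mean log2 CPM was 6.94 and 6.18 in wild-type females 2 and 3. The list stood at 4.55, 4.69 and 3.70 in non-tumour 1, 2 and 3, and at 4.29, 3.705 and 2.05 in tumours 1, 2 and 3. Its test in this comparison is not reported here. The Mup, Sult2a, Cyp3a, Cyp2b, Cyp2c, Cyp4a12, Gsta, Gstm and Serpina1 families hold near-identical copies, so the split of reads among their members is uncertain here and in every comparison below.

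Of the 20 genes of the NRF2 and glutathione list, 12 rose and none fell, with Srxn1 at 2.17 ± 0.39 beside Nqo1 and Gstm3, and 15 were higher and 2 lower adjusted over the list alone. The list passed with a preset correlation (camera adjusted p = 1.83e-09) but not otherwise (adjusted p = 0.188 with an estimated correlation). Of the 22 CAR and PXR target enzymes, which take part in drug and steroid metabolism, 5 rose, among them Cyp3a11 (4.08 ± 0.65), Cyp2c55 (4.97 ± 1.01) and Alas1 (1.62 ± 0.35). The count adjusted over the list alone was 7, and the adjusted p = 0.479 with an estimated correlation. Of the 23 macrophage and monocyte genes 5 rose, among them Cd14 (3.03 ± 0.63), Csf1r (1.26 ± 0.28) and Lgals3 (2.59 ± 0.57). There were 11 adjusted over the list alone, with adjusted p = 0.418 with an estimated correlation. Of the 22 cholangiocyte genes, markers of bile duct epithelium, Mmp7 rose (3.52 ± 0.77), and 3 adjusted over the list alone, with adjusted p = 0.451 with an estimated correlation.

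Of the 24 cholesterol synthesis genes 4 fell, among them Hsd17b7 (−1.69 ± 0.37), Fdps (−2.99 ± 0.71) and Idi1 (−2.91 ± 0.76), and the median log2 fold change of the list was −1.26. There were 7 adjusted over the list alone, with adjusted p = 0.479 with an estimated correlation. The mean log2 CPM of this list was 6.43 and 6.69 in wild-type females 2 and 3 and 4.43, 6.05 and 5.06 in non-tumour 1, 2 and 3, whose scores of daily clock genes, described with the male groups, were 1.36 and 0.382 and −1.04, 2.90 and 4.48. Of the 13 bile acid sensing genes 4 fell, among them the nuclear receptor Nr1i3 (−1.89 ± 0.37), and 6 adjusted over the list alone, with adjusted p = 0.255 with an estimated correlation. Bile acid handling genes mostly kept below the threshold. Among 19 bile acid synthesis genes Acot8 fell (−0.84 ± 0.23), and Cyp7a1, the rate-limiting enzyme of the classical pathway, stood at 169 ± 66.2 CPM against 317 ± 170 CPM (edgeR adjusted p = 0.435). Among 9 hepatocyte uptake carriers Slco1b2 fell (−1.13 ± 0.27). Among 14 export pumps and carriers Slc51b, a basolateral bile acid carrier subunit, rose (5.08 ± 1.02) and Abcc6 fell (−1.18 ± 0.31). Adjusted over the list alone, 1 synthesis gene was lower, 1 uptake carrier was lower, and 3 export genes were higher and 4 lower. These 3 lists did not pass with the preset correlation (camera adjusted p = 0.315, 0.507 and 0.73) or otherwise (adjusted p = 0.838, 0.838 and 0.893 with an estimated correlation).

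The edgeR quasi-likelihood test called 743 genes in this comparison, 339 higher and 404 lower. This balance depended on the processing: 429 were higher and 363 lower with upper-quartile scaling, and 1128 and 611 without a low-count filter. The counts rested on single libraries: 17 genes passed without wild-type female 3, 184 without wild-type female 2, 146 without non-tumour 3 and 198 without non-tumour 1. Of the 16 genes named by size of change, Sult2a8, Cyp3a16, E2f8 and Abcb11 passed with each library left out in turn, while 12 lost the call without wild-type female 3, 9 without wild-type female 2, 6 without non-tumour 3, 5 without non-tumour 1 and 1 (Sult5a1) without non-tumour 2. Without wild-type female 3, 53 of the 57 called genes covered by the naming rule lost their call, without wild-type female 2 it was 43, without non-tumour 3 it was 38, and without non-tumour 1 it was 32. The members past the threshold in NRF2 and glutathione, CAR and PXR target enzymes, macrophage and monocyte, cholesterol synthesis and bile acid sensing, in that order, became 0, 1, 0, 0 and 0 without wild-type female 3, and 3, 0, 1, 0 and 1 without wild-type female 2. They became 5, 2, 2, 0 and 0 without non-tumour 3, and 6, 3, 1, 0 and 0 without non-tumour 1, while leaving out non-tumour 2 raised the cholesterol synthesis count to 12. With the replicate number as a block, which does not pair these groups, 93 genes passed and 43 of the 57 lost their call. DESeq2 called 1942 genes and limma-voom 3397.

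The second comparison set tumour tissue against non-tumour liver of knockout females. No gene passed edgeR's test, with 1217 genes at an unadjusted p under 0.05 where chance gives 894. DESeq2 called 29 genes, limma-voom 0, and edgeR without a low-count filter 338. With the preset correlation 14 of 38 gene lists passed as sets, and 0 with an estimated correlation. The urea cycle and amino acid breakdown genes had a median log2 fold change of −0.74, with 23 of 24 members lower and Cps1 at −1.88 ± 0.61. The pericentral and beta-catenin target genes had a median of −0.66, with 17 of 18 lower and Cyp2e1 at −1.79 ± 0.52. The lipogenesis genes had a median of 1.21, with 17 of 18 higher and Elovl6 at 1.99 ± 0.71, Acly at 1.71 ± 0.63 and Acaca at 1.62 ± 0.58. These shifts rested on numbers 2 and 3: the mean log2 level of the list in tumour minus non-tumour was −0.17, −1.75 and −1.22 in numbers 1, 2 and 3 for urea cycle, −0.14, −1.44 and −1.57 for pericentral and −0.25, 1.42 and 1.48 for lipogenesis genes. Mitochondrially encoded genes held 33.0, 30.6 and 29.1% of the counts in tumours 1, 2 and 3 and 19.1, 34.2 and 16.7% in non-tumour 1, 2 and 3, with differences in the mean log2 level of 0.97, 0.03 and 1.24, so the numbers also differed in this measure of the sample.

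The camera adjusted p with the preset correlation was 9.05e-10 for urea cycle and amino acid breakdown, 3e-06 for pericentral and beta-catenin target and 3.82e-05 for lipogenesis. All 3 calls were lost otherwise (adjusted p = 0.525, 0.525 and 0.62 with an estimated correlation). CAR and PXR target enzymes had a median of −0.75, with Cyp2c37 at −2.62 ± 0.54 and Cyp2a5 at −2.36 ± 0.65 (adjusted p = 0.525 with an estimated correlation). Bile acid synthesis genes had a median of −0.39, with Cyp7a1 at 39.1 ± 29.5 CPM in tumours and 169 ± 66.2 CPM in non-tumour liver, Cyp7b1 at −1.78 ± 0.67 and Akr1c6 at −1.44 ± 0.39 (adjusted p = 0.525 with an estimated correlation). Fibrosis and stellate cell genes had a median of 0.59, with Col4a2 at 1.52 ± 0.42 and Sparc at 1.49 ± 0.49, and endothelial cell genes a median of 0.58, with Vwf at 1.19 ± 0.43 and Tie1 at 1.08 ± 0.34 (adjusted p = 0.63 and 0.525 with an estimated correlation). Hepatocyte identity genes had a median of −0.41, with 18 of 25 lower, Kupffer cell genes a median of −0.41, with 10 of 13 lower and Vsig4 at −0.94 ± 0.49, and adipocyte genes a median of 0.91, with 4 of 5 higher and Fabp4 at 2.28 ± 0.50 (camera adjusted p = 0.00117, 0.0367 and 0.00483; adjusted p = 0.695, 0.62 and 0.358 with an estimated correlation). The mean log2 level in tumour minus non-tumour was 0.04, −0.94 and −0.80 in numbers 1, 2 and 3 for Kupffer cell genes. For fibrosis and stellate cell genes it was 0.06, 1.11 and 0.45, so both shifts were nearly absent in number 1. The endothelial, hepatocyte identity and adipocyte lists kept their sign in each number. The cell cycle list (median 0.47) and the liver tumour and oncofetal list (median 0.00) did not pass (camera adjusted p = 0.0718 and 0.45, and adjusted p = 0.846 for both with an estimated correlation). Adjusted over the list alone, 6 CAR and PXR target enzymes, 2 bile acid synthesis genes, 1 urea cycle gene and 1 hepatocyte identity gene were lower, 1 adipocyte gene was higher, and 0 genes passed in the Kupffer cell, pericentral, lipogenesis, fibrosis, endothelial, cell cycle and oncofetal lists.

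Tumour and non-tumour libraries with the same number varied together, and with the number as a block 2 genes passed, both higher in tumours. These were Psapl1, with 0, 5065 and 33 counts in tumours 1, 2 and 3 and 0, 1 and 0 in non-tumour liver, so that tumour 2 carries its mean, and the cytochrome P450 gene Cyp4a12a, with 5, 83 and 94 counts against 0, 6 and 2. Both were named after their values were seen, and with the block 0 genes passed without number 2 and 0 without number 3. The block changed no list call. Without tumour 1, 42 genes passed, and without non-tumour 1, 2 passed. With both libraries of number 1 left out, an alternative chosen after seeing the data, 20 genes passed, and 46 with the block as well.

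The third comparison set tumours against wild-type female liver. Sult2a8 fell to 1.68 ± 0.172 CPM and Cyp3a16 to 0.569 ± 0.309 CPM, with log2 fold changes of −6.79 ± 0.52 and −7.85 ± 0.62 (edgeR adjusted p = 2.3e-05 and 0.000131). Gstm3 rose to 1187 ± 625 CPM (6.22 ± 0.81) and Nqo1 to 26.1 ± 4.31 CPM (2.45 ± 0.40). Cyp7a1 fell from 317 ± 170 to 39.1 ± 29.5 CPM (−3.02 ± 0.64, edgeR adjusted p = 0.0124; n = 2 and 3).

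By size of change, Gsta1 (8.52 ± 1.68), Smpd3 (7.29 ± 1.15) and Sdcbp2 (6.84 ± 1.14) rose. Cidea, a lipid droplet gene, and Sprr1a had no counts in wild-type females and stood at 16.6 ± 23.2 and 6.26 ± 7.68 CPM in tumours, with 0.124 and 0.433 CPM in tumour 1. Sprr1a was at least 2.61-fold higher over a floor of 3 counts per library, and tumour 1 lay under the floor for Cidea. Wisp2, Ly6c1 and Dnah1 had 1 to 3 counts in all in wild-type females, and their ratios had counting intervals of 37.5 to 8337, 31.7 to 955 and 29.6 to 424. Cyp3a44 (−6.76 ± 1.53), Sult2a3 (−5.86 ± 1.40), P2ry4 (−5.59 ± 1.07), Rgr (−5.35 ± 1.21), Gbp10 (−5.05 ± 1.18) and Hao2 (−5.02 ± 1.04) fell. Xist fell as well (−1.21 ± 0.33, edgeR adjusted p = 0.036). The wild-type female libraries also stood apart in noncoding RNA. Genes of long intergenic RNA held 0.819 and 1.01% of their counts, against at most 0.742% in any other library. The share was not taken without Xist, so it gives no separate evidence on Xist. Malat1, another long noncoding RNA, stood at 1306.5 and 1707.4 CPM in wild-type females 2 and 3, against 359 to 834 CPM in knockout females. It stood at 605 to 816 CPM in knockout males and 129 to 181 CPM in wild-type males. Whether this feature of the libraries moved Xist or other genes was not tested.

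Of the 20 NRF2 and glutathione genes 11 rose, with Srxn1 at 2.01 ± 0.38, and 14 were higher and 1 lower adjusted over the list alone, with adjusted p = 0.282 with an estimated correlation. Macrophage and monocyte genes rose in 8 of 23 cases, among them Csf1r (1.51 ± 0.28), Lgals3 (2.98 ± 0.58) and C1qa (2.09 ± 0.45), and in 12 adjusted over the list alone (adjusted p = 0.373 with an estimated correlation). Fibrosis and stellate cell genes rose in 5 of 39 cases, among them Col4a2 (2.38 ± 0.50), Timp2 (1.58 ± 0.35) and Col4a1 (2.21 ± 0.51), and in 11 adjusted over the list alone (adjusted p = 0.55 with an estimated correlation). Of 22 cholangiocyte genes Mmp7 (3.34 ± 0.76), Krt7 (2.41 ± 0.66), Krt19 (2.65 ± 0.74) and 1 more rose, and 8 adjusted over the list alone, with adjusted p = 0.373 with an estimated correlation.

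Beside Cyp7a1, Akr1c6 (−1.82 ± 0.43) and Acot8 fell among the 19 bile acid synthesis genes, 4 adjusted over the list alone (adjusted p = 0.55 with an estimated correlation). The uptake carriers Slco1b2 (−1.73 ± 0.27) and Slc10a5 (−3.23 ± 0.62) fell, 2 adjusted over the list alone (camera adjusted p = 0.227; adjusted p = 0.677 with an estimated correlation). Of the 14 export pumps and carriers Slc51b (6.14 ± 1.05) and Abcg2 (1.48 ± 0.34) rose, and Abcc2 (−1.59 ± 0.34), Abcc6 (−1.34 ± 0.31), Abca1 (−1.06 ± 0.23), Abcg5 (−1.17 ± 0.31) and Abcg8 (−1.61 ± 0.37) fell. The counts adjusted over the list alone were also 2 and 5, with camera adjusted p = 0.864 and adjusted p = 0.928 with an estimated correlation. Of 24 cholesterol synthesis genes 5 fell, among them Idi1 (−4.11 ± 0.80), and 15 fell adjusted over the list alone (adjusted p = 0.55 with an estimated correlation). Among 23 liver tumour and oncofetal genes Anxa2 (3.11 ± 0.55) and S100a11 (3.02 ± 0.85) rose and the alpha-fetoprotein gene Afp fell (−2.51 ± 0.63). Adjusted over the list alone 8 were higher and 2 lower, with adjusted p = 0.373 with an estimated correlation.

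The edgeR test called 1718 genes here, 705 higher and 1013 lower. Without wild-type female 3 the count was 157, without wild-type female 2 it was 701, without tumour 2 it was 799 and without tumour 3 it was 905. Of the 16 genes named by size, Sult2a8 and Cyp3a16 passed with each library left out, while 14 lost the call without wild-type female 3, 9 without wild-type female 2, 7 without tumour 3, 6 without tumour 2 and 3 without tumour 1. Of the 87 called genes covered by the naming rule, 73 lost their call without wild-type female 3, 50 without wild-type female 2, 36 without tumour 2 and 33 without tumour 3. The members past the threshold in NRF2 and glutathione, macrophage and monocyte, fibrosis and stellate cell, cholangiocyte, bile acid synthesis, export pumps and carriers and cholesterol synthesis, in that order, became 1, 0, 0, 0, 1, 0 and 1 without wild-type female 3. Without wild-type female 2 the 6 that moved became 5 for NRF2 and glutathione, 3 for macrophage and monocyte, 1 for fibrosis and stellate cell, 1 for cholangiocyte, 0 for bile acid synthesis and 2 for cholesterol synthesis. Without tumour 2, macrophage and monocyte went to 4, fibrosis and stellate cell to 3, cholangiocyte to 1, bile acid synthesis to 0, export pumps and carriers to 1 and cholesterol synthesis to 2. Without tumour 3, NRF2 and glutathione went to 7, fibrosis and stellate cell to 3 and cholangiocyte to 1, and without tumour 1, fibrosis and stellate cell went to 8 and cholesterol synthesis to 3. DESeq2 called 3030 genes and limma-voom 4599.

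**Figure D2:**
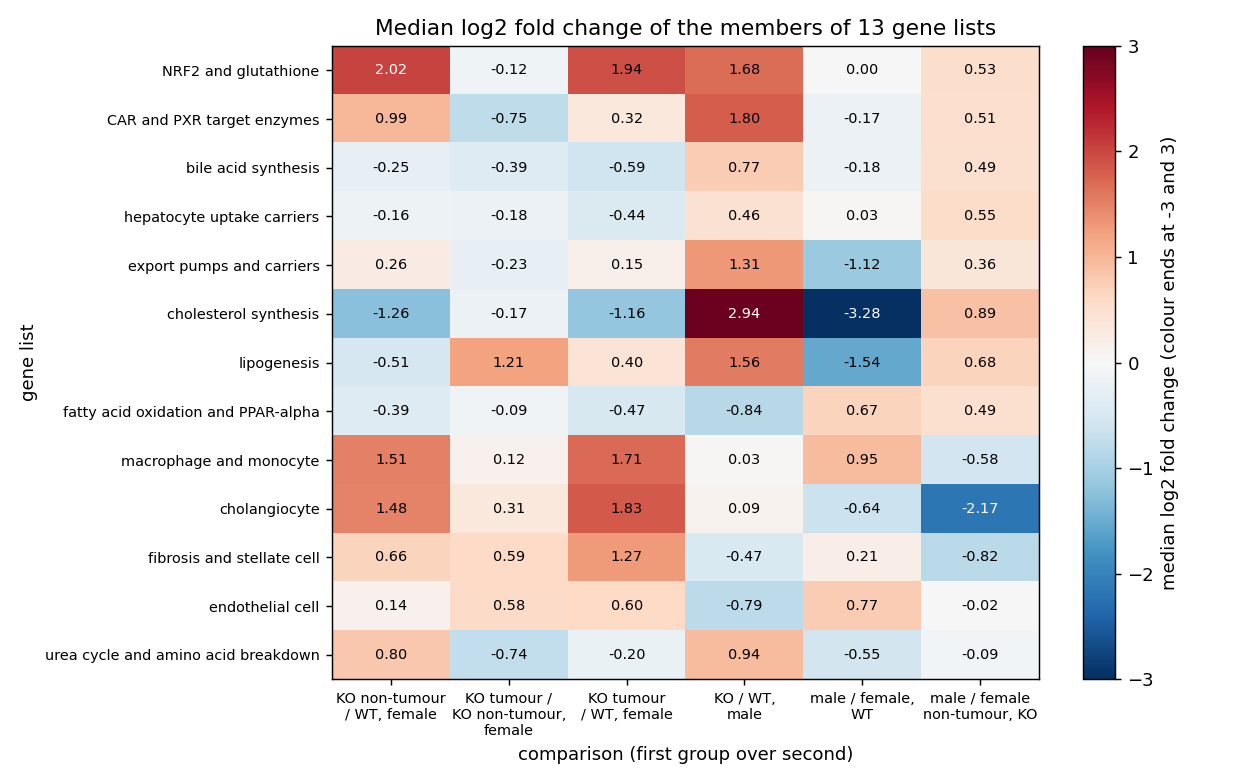
Median log2 fold change of the members of 13 gene lists (vertical axis) in 6 comparisons (horizontal axis), with the value in each cell and colour from −3 to 3. Cholesterol synthesis genes had a median of −1.26 between non-tumour knockout and wild-type females and 2.94 between knockout and wild-type males, and NRF2 and glutathione genes had medians of 2.02 and 1.68.

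The fourth comparison set knockout against wild-type males. Of the cholesterol synthesis genes Cyp51 went from 13.6 ± 1.57 to 128 ± 23.5 CPM (3.23 ± 0.33, edgeR adjusted p = 4.33e-05), Sqle, squalene epoxidase, by 4.19 ± 0.43, and Mvk, mevalonate kinase, by 4.49 ± 0.50 on the log2 scale. Of the 24 genes of this list 23 rose (adjusted p = 0.41 with an estimated correlation, and 23 adjusted over the list alone), and 6 with a clock score as a covariate. Some bile acid synthesis genes rose too, with Cyp7a1 going from 6.25 ± 4.34 to 176 ± 15.4 CPM (4.82 ± 0.66), Akr1d1 by 4.20 ± 0.31 and Cyp2c70 by 3.84 ± 0.53. Gstm3 went from 5.05 ± 2.69 to 1211 ± 601 CPM (7.91 ± 0.73) and Nqo1 from 2.38 ± 0.778 to 35.8 ± 4.34 CPM (3.92 ± 0.37; n = 3 each).

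By size of change, genes without counts in any wild-type male led the rise. Over a floor of 3 counts per library, Ptgds, a prostaglandin synthase, was at least 844-fold higher (304 ± 251 CPM in knockouts), Clec2h 159-fold, Tmprss4 121-fold, Slc51b 97.1-fold, the glutamate transporter gene Slc1a1 63.8-fold, Gipc2 54.2-fold and Sult1e1 32.3-fold. These limits cover counting error alone, and the wild-type male libraries hold few weakly counted genes. Per3 had 0, 47 and 20 counts and Dbp 0, 22 and 19 in wild-type males 1, 2 and 3, so a 0 in these libraries does not show a level under the floor. Pdgfrl (−6.70 ± 0.72), Fam209 (−6.29 ± 0.81), the major urinary protein gene Mup11 (−6.27 ± 0.79), Rad51b (−4.79 ± 0.69), Slc16a13 (−4.57 ± 0.87), Serpina1e (−4.42 ± 1.39) and Acnat2 (−4.14 ± 0.58) fell. Cidea also fell, with 1 count in the 3 knockouts, a ratio with a counting interval of 174.9 to 38600.

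Of the 24 cholesterol synthesis genes 23 rose, the same number adjusted over the list alone (camera adjusted p = 2.29e-13 with the preset correlation; adjusted p = 0.41 with an estimated correlation). Of the 20 NRF2 and glutathione genes 14 rose, among them Gstm1 (3.90 ± 0.42), and 15 adjusted over the list alone (adjusted p = 0.358 with an estimated correlation). CAR and PXR target enzymes rose in 16 of 22 cases, among them Papss2 (2.52 ± 0.34), Cyp2a5 (5.46 ± 0.75) and Cyp3a25 (3.13 ± 0.47), while Gadd45b, a stress-response gene, fell (−1.58 ± 0.32). The counts adjusted over the list alone were also 16 and 1, with adjusted p = 0.623 with an estimated correlation. Of the 19 bile acid synthesis genes 9 rose and Cyp46a1 fell (−1.64 ± 0.54), with 9 and 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.165; adjusted p = 0.917 with an estimated correlation). Of the 9 uptake carriers Slc10a1 (1.61 ± 0.34), Slc10a5 (4.46 ± 0.66), Slco1a4 (2.46 ± 0.49) and Slc22a7 (2.33 ± 0.74) rose and Slco1a1 fell (−2.57 ± 0.43). Adjusted over the list alone the counts were 4 and 1, and this list did not pass either (camera adjusted p = 0.52; adjusted p = 0.917 with an estimated correlation). Of the 14 export pumps and carriers 8 rose, among them Abcc2 (1.46 ± 0.32), Abcc3 (1.46 ± 0.33), Abcc4 (3.44 ± 0.60) and Atp8b1 (1.58 ± 0.26), and 9 adjusted over the list alone (adjusted p = 0.358 with an estimated correlation).

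Lipogenesis genes rose in 7 of 18 cases, among them Acss2 (2.80 ± 0.42), Pklr (3.65 ± 0.55) and Fads1 (2.23 ± 0.37), and in 9 adjusted over the list alone (adjusted p = 0.917 with an estimated correlation). Of the 26 fatty acid oxidation and PPAR-alpha genes 8 fell, among them Cyp4a14 (−3.49 ± 0.35), Crat (−1.85 ± 0.31) and Ehhadh (−2.81 ± 0.50), and Cpt1a rose (0.94 ± 0.30). Adjusted over the list alone 9 fell and 1 rose, with adjusted p = 0.623 with an estimated correlation. Urea cycle and amino acid breakdown genes rose in 9 of 24 cases, among them Bhmt (2.73 ± 0.38) and Otc (2.02 ± 0.34), with 13 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.069; adjusted p = 0.917 with an estimated correlation). Endothelial cell genes fell in 6 of 18 cases, among them Stab1 (−1.63 ± 0.28), Clec4g (−1.27 ± 0.25) and Pecam1 (−1.18 ± 0.30), and in 9 adjusted over the list alone (adjusted p = 0.36 with an estimated correlation). Of 23 macrophage and monocyte genes 0 passed edgeR's test with all libraries, and 0 adjusted over the list alone (median 0.03; adjusted p = 0.995 with an estimated correlation). This rested on wild-type male 3, without which 9 rose, also 9 adjusted over the list alone, with a median of 0.85 (adjusted p = 0.756 with an estimated correlation).

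The edgeR test called 3688 genes between knockout and wild-type males, 2558 higher and 1130 lower, with 2462 to 4055 as each library was left out. Among the list counts, CAR and PXR target enzymes went to 10 without knockout male 3, wild-type male 2 or wild-type male 3, and endothelial cell to 3 without knockout male 1 or knockout male 3. Of the 16 genes named by size of change, Sult1e1 lost its call whichever of the 6 libraries was left out, Serpina1e with each of them but wild-type male 3, and Cidea with each knockout library. Of the 122 called genes covered by the naming rule, the number losing their call ran from 18 (without knockout male 2) to 39 (without knockout male 1). A fit of the compared groups alone called 2262 genes. The median log2 fold change of all genes was 0.113 with TMM and 0 with RLE or upper-quartile scaling, and the share of calls that were higher was 69.4%, 59.8% and 59.9%. With either of the latter, 6 bile acid synthesis genes and 13 CAR and PXR target enzymes rose.

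The wild-type male libraries stood apart from the other 11 in several measures. They held 1440 to 2009 genes with 1 to 9 counts, against 3676 to 6638 elsewhere. Of their counts 1.47 to 2.91% lay on rRNA genes, the mitochondrial ones included, against 0.157 to 0.594%. Genes of long intergenic RNA held 0.297 to 0.333%, against 0.372 to 1.01% elsewhere. Malat1 stood at 129 to 181 CPM, against 359 to 1707 CPM. Wild-type male 3 also stood apart from wild-type males 1 and 2 in immune and cell cycle lists. Its mean log2 CPM was 3.80 for macrophage and monocyte genes against at most 1.94, 3.41 for T and NK cell genes against −0.90 and −0.52, 6.89 for B and plasma cell genes against 0.22 and 0.45, 5.18 for MHC class II and dendritic cell genes against 1.49 and 1.21, and 3.23 for cell cycle genes against −0.65 and −0.59. Between the male groups the median log2 fold changes of the last 4 lists were −1.97, −2.41, −1.45 and −1.28 with this library and 0.69, 2.75, 1.63 and 1.41 without it, so that their sign hinged on this library, a check made after seeing the data. A score of daily clock genes, the mean log2 CPM of 8 evening genes such as Dbp and Per3 minus that of 4 morning genes such as Arntl and Npas2, was −2.82 to −2.37 in wild-type males and 2.57 to 3.51 in knockout males. With this score as a covariate, chosen after seeing the data, 278 genes passed between the male groups. Cholesterol synthesis then had 6 members past the threshold, NRF2 and glutathione 5, bile acid synthesis 4, CAR and PXR target enzymes 1, export pumps and carriers 2, uptake carriers 2, lipogenesis 0, fatty acid oxidation and PPAR-alpha 1, urea cycle and amino acid breakdown 1 and endothelial cell 0. Of the 16 genes named by size of change, Ptgds, Tmprss4, Slc51b, Gipc2, Slc1a1, Pdgfrl and Fam209 still passed.

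**Figure D3:**
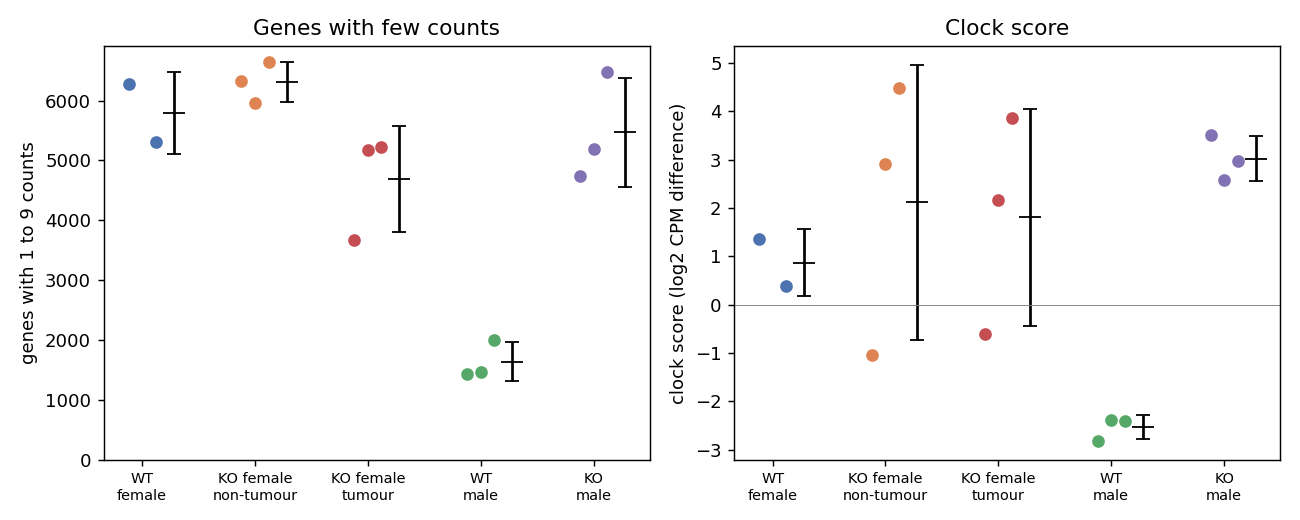
Genes with 1 to 9 counts (left) and clock score in log2 CPM (right) for each library, by group; each point is 1 library and the bar is the group mean ± SD. The wild-type male libraries lie at 1440 to 2009 genes and at scores of −2.82 to −2.37, below all other libraries in both.

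The fifth comparison tested whether the knockout effect differed between the sexes, as the female effect in non-tumour liver minus the male effect. Of the cholesterol synthesis genes Sqle went from 64.6 ± 6.03 to 32.3 ± 12.1 CPM in females (n = 2 and 3) and from 3.24 ± 0.748 to 59.0 ± 8.75 CPM in males (n = 3 each), a difference of −5.19 ± 0.58 (edgeR adjusted p = 0.000265). Mvk (−5.89 ± 0.67) and Cyp51 (−3.90 ± 0.46) also differed. Cyp7a1 differed by −5.72 ± 0.88 and Akr1d1 by −3.82 ± 0.42. Mmp7, a matrix metalloproteinase, rose in females from 2.52 to 28.6 ± 6.12 CPM and stood in males at 2.58 ± 1.36 in wild type and 0.564 ± 0.588 CPM in knockout liver (difference 5.72 ± 1.06).

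By size of difference, Pdgfrl (6.05, edgeR adjusted p = 0.00216), Elovl3 (5.68 ± 0.95), Tuba8 (5.19 ± 1.26) and Cdkn1a (4.97 ± 1.16), a cyclin-dependent kinase inhibitor, had the higher female than male effect beside Mmp7. Elovl3, a fatty acid elongase, fell in males from 400 ± 121 to 52.6 ± 25.0 CPM and stood at 0.76 ± 0.016 and 5.22 ± 4.28 CPM in females (edgeR adjusted p = 0.0563 there). Ptgds, Cyp3a16, Cyp2g1, Ptp4a1 (ENSMUSG00000026064) and R3hdml lay lowest, all without counts in wild-type males, so that their fitted differences are no bound. Cyp3a16 went from 135 ± 70.9 to 1.78 ± 0.427 CPM in females and from 0 to 1.36 ± 1.08 CPM in males. Sult2a8 also differed (−6.21 ± 0.62), standing at 294 ± 58.8 CPM in wild-type and 226 ± 37.0 CPM in knockout males.

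Of the 24 cholesterol synthesis genes 23 passed with the lower female effect, the same number adjusted over the list alone (median −4.07; camera adjusted p = 4.03e-17 with the preset correlation; adjusted p = 0.384 with an estimated correlation). Lipogenesis genes passed in 6 of 18 cases, all with the lower female effect, with Pklr at −4.76 ± 0.75 and Srebf1 at −4.04 ± 0.81, and 8 adjusted over the list alone (adjusted p = 0.635 with an estimated correlation). Macrophage and monocyte genes passed in 5 of 23 cases with the higher female effect, among them Cd14 (3.61 ± 0.79), Itgam (4.38 ± 1.06) and C1qa (2.26 ± 0.57), with 8 higher and 1 lower adjusted over the list alone (adjusted p = 0.604 with an estimated correlation). The male side of this difference rests on wild-type male 3, which stood apart in immune lists, and without it 5 macrophage and monocyte genes were higher and 2 lower, with the median going from 1.48 to 0.75. Among 22 cholangiocyte genes Mmp7, Krt7 (4.23 ± 0.87) and St14 (3.44 ± 0.87) passed, 5 adjusted over the list alone (adjusted p = 0.594 with an estimated correlation). Among 14 export pumps and carriers Abca1 (−1.80 ± 0.31), Abcc2 (−2.47 ± 0.47), Abcg5 (−1.78 ± 0.42), Abcg8 (−2.02 ± 0.50) and Atp8b1 (−1.38 ± 0.38) passed, with 7 lower and 1 higher adjusted over the list alone (adjusted p = 0.384 with an estimated correlation). Of the 19 bile acid synthesis genes 4 passed with the lower female effect, Akr1c6 (−2.26 ± 0.58) and Cyp2c70 (−2.73 ± 0.71) beside Cyp7a1 and Akr1d1, and 5 adjusted over the list alone (adjusted p = 0.604 with an estimated correlation). Among NRF2 and glutathione genes Srxn1 passed upward (1.80 ± 0.49) and Gstm1 downward (−1.95 ± 0.56), with 1 and 4 adjusted over the list alone (camera adjusted p = 0.438; adjusted p = 0.788 with an estimated correlation).

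The edgeR test called 1945 genes for this difference, 393 with the higher and 1552 with the lower female effect. The higher share was 20.2% with TMM and 32.7% with upper-quartile scaling, which moved the median of all genes from −0.0666 to 0.0903. The count was 576 without wild-type female 3, 1016 without wild-type female 2, 884 without non-tumour 1 and 1228 without knockout male 1. The cholesterol synthesis count stayed within 1.5 times of 23 in each of these. Lipogenesis went to 3 without wild-type female 3, macrophage and monocyte to 0 without wild-type female 3, to 2 without wild-type female 2, to 3 without non-tumour 1 or knockout male 2 and to 8 without wild-type male 2. Bile acid synthesis went to 2 without either wild-type female or non-tumour 3. Cholangiocyte went to 1 without wild-type female 3 and to 5 without knockout male 2, wild-type male 2 or wild-type male 3, and export pumps and carriers to 2 without wild-type female 3 and 3 without non-tumour 1. Of the 10 genes named by size, Tuba8, Cdkn1a and R3hdml lost the call without either wild-type female and Ptgds without wild-type female 3. Of the 77 called genes covered by the naming rule 47 lost their call without wild-type female 3, and 31 without wild-type female 2. With the clock score as a covariate 421 genes and 16 cholesterol synthesis genes passed, and DESeq2 called 3039 genes and limma-voom 3333.

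Across the 17874 genes, the female non-tumour and the male knockout effects had a Pearson r of −0.0291 and a Spearman rho of −0.059, with genes not being independent replicates. No library entered both. The 2 comparisons shared 134 genes that rose in both, where independent lists would share 48.5, and 72 that fell in both, against 25.5. A further 96 fell in females and rose in males, against 57.8, and 11 did the opposite, against 21.4.

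**Figure D4:**
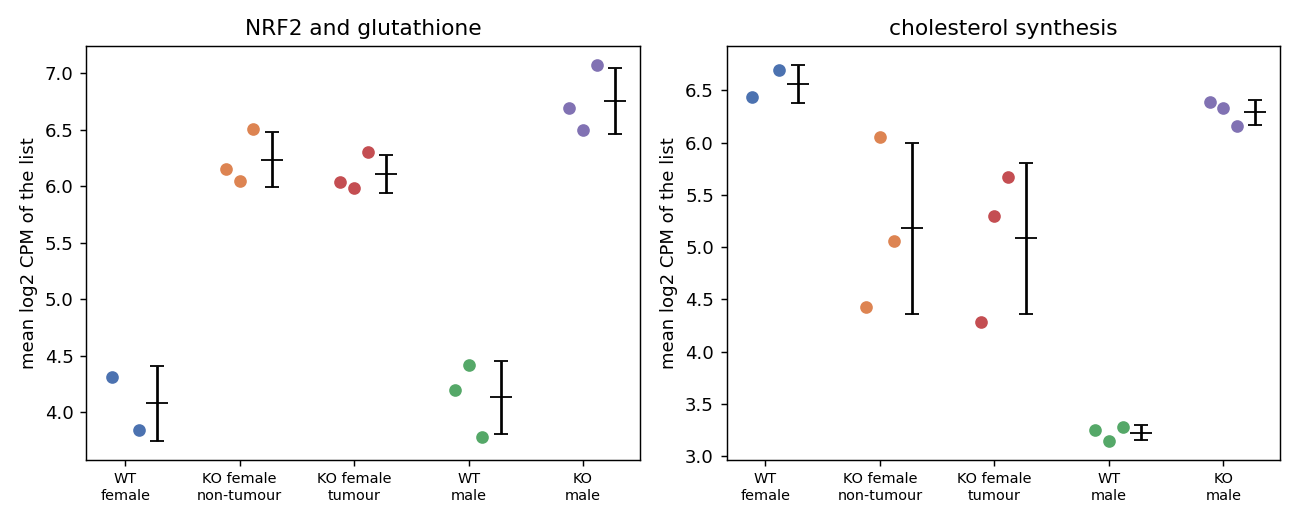
Mean log2 CPM of the NRF2 and glutathione list (left) and the cholesterol synthesis list (right) in each library, by group; each point is 1 library and the bar is the group mean ± SD. All 9 knockout libraries lie above all 5 wild-type libraries in the first list, and the wild-type males lie lowest in the second.

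The sixth comparison set wild-type males against wild-type females. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at least 374-fold, 280-fold, 55.8-fold and 45.6-fold higher in males, over a floor of 3 counts per library in females. Mup12 (9.84 ± 2.16) and Mup11 (9.28 ± 1.12) were higher in males, as were Elovl3 (9.02 ± 0.93) and Cyp4a12a (9.20 ± 1.14), and Cidea and Cfd were at least 32.0-fold and 25.7-fold higher. A1bg, Sult2a1, Cyp2b13, Sult2a2, Cyp3a16, Cyp3a44 and Hao2 had no counts in wild-type males and were at least 75.4-fold, 707-fold, 538-fold, 517-fold, 454-fold, 233-fold and 202-fold lower there (n = 3 males and 2 females). A1bg stood at 372 ± 506 CPM in females, with 14.1 CPM in wild-type female 3, and the doubt about a 0 in the wild-type male libraries holds for these limits too.

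Of 23 female-biased liver genes 19 were lower in males, and all 23 adjusted over the list alone (adjusted p = 0.115 with an estimated correlation). Of 25 male-biased liver genes 15 were higher and Keg1 was lower (−1.36 ± 0.31), with 19 and 1 adjusted over the list alone (adjusted p = 0.169 with an estimated correlation). Cholesterol synthesis genes were lower in males in 21 of 24 cases, among them Sqle (−4.32 ± 0.45), Mvk (−4.90 ± 0.52) and Sc5d (−3.37 ± 0.39), and 23 adjusted over the list alone (adjusted p = 0.383 with an estimated correlation). Cyp7a1 (−5.67 ± 0.71) and Akr1d1 (−3.21 ± 0.32) were lower and Cyp7b1 higher (2.58 ± 0.77) in males, with 5 lower and 1 higher among 19 bile acid synthesis genes, the same numbers adjusted over the list alone (camera adjusted p = 0.57; adjusted p = 0.929 with an estimated correlation). The edgeR test called 4137 genes, 1257 higher and 2880 lower in males, with 1290 without wild-type female 3 and 2299 without wild-type female 2. Male-biased liver genes went to 7 without wild-type female 3, and bile acid synthesis to 3 without either wild-type female, wild-type male 2 or wild-type male 3. Cidea, Cfd and Cyp2b13 lost their calls without either female, Mup12 and A1bg without wild-type female 3, A1bg also whichever male was left out and Cyp2b13 without wild-type male 3. The groups compared alone gave 1824 genes, and the clock score as a covariate 1801. The wild-type males of this comparison are the libraries with 1440 to 2009 genes at 1 to 9 counts, and the median of all genes was −0.116 with TMM and −0.0109 with RLE scaling. Their clock scores ran from −2.82 to −2.37, against 1.36 and 0.382 in wild-type females 2 and 3. Malat1 stood at 129 to 181 CPM in these males and at 1306.5 and 1707.4 CPM in wild-type females 2 and 3. Cfd belongs to the adipocyte list, whose mean log2 CPM was 4.46 ± 0.428 in wild-type males and 2.785 ± 0.205 in wild-type females (n = 3 and 2). Outside the Y-linked genes a call may therefore reflect sex or these features of the libraries.

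The seventh comparison set knockout males against non-tumour liver of knockout females. Besides the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, at least 291-fold, 256-fold, 147-fold and 112-fold higher over 3 counts per library, Sult2a8 was higher in males (226 ± 37.0 against 1.97 ± 1.66 CPM; 6.85 ± 0.51, edgeR adjusted p = 3.75e-06), as were Cyp4a12a (447 ± 136 against 0.149 ± 0.185 CPM; 11.57 ± 1.02) and Sult2a7 (6.75 ± 1.14). Mup11 had 2 counts in the females, and its ratio had a counting interval of 51.3 to 1552. Lower in males were Cux2, a transcription factor of female liver (−5.86 ± 0.59), Mmp7 (−5.68 ± 0.76), Cyp2b9 (−9.43 ± 1.48), Sult2a2 (−9.08 ± 1.25), Cyp2c40 (−5.23 ± 0.92) and Cyp17a1 (−4.22 ± 0.74). Sult2a1 had 1 count in the males, a ratio with a counting interval of 2492 to 548600, and Sult2a5 had none and was at least 43.3-fold lower (n = 3 each). Abcb11 was higher in males (1.69 ± 0.33, edgeR adjusted p = 0.0404).

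Of 23 female-biased liver genes 6 were lower in knockout males, 12 adjusted over the list alone, and of 25 male-biased liver genes 7 were higher, among them Keg1 (3.25 ± 0.30) and Ugt2b38 (3.78 ± 0.67), 21 adjusted over the list alone. Both lists passed under either correlation (adjusted p = 0.0194 for each with an estimated correlation). The female-biased list stood lower in non-tumour knockout than in wild-type females, as given with the first comparison. Of 22 cholangiocyte genes Mmp7, Cldn7 (−3.50 ± 0.62) and Krt7 (−3.28 ± 0.59) were lower, 16 adjusted over the list alone, and this list passed too (adjusted p = 0.0348 with an estimated correlation). Of 24 cholesterol synthesis genes Cyp51 was higher (1.53 ± 0.31), 1 adjusted over the list alone (adjusted p = 0.238 with an estimated correlation). The edgeR test called 70 genes, 37 higher and 33 lower, with 19 without knockout male 1, 22 without knockout male 3, 25 without non-tumour 1 and 143 without knockout male 2. The counts for male-biased, female-biased and cholangiocyte genes, in that order, became 2, 1 and 1 without knockout male 1 and again without knockout male 3. Without non-tumour 1 the male-biased and female-biased counts became 2 and 3, without non-tumour 2 the male-biased count became 3, and without knockout male 2 the male-biased and cholangiocyte counts became 11 and 9. Of 16 genes named by size, Ddx3y, Eif2s3y, Kdm5d, Uty, Cyp4a12a, Sult2a8, Cux2 and Mmp7 passed with each library left out. The other 8 lost the call without knockout male 1 and without knockout male 3, 6 of them without non-tumour 1, 3 without non-tumour 2, 3 without non-tumour 3 and 2 without knockout male 2. DESeq2 called 470 genes, limma-voom 710 and the groups compared alone 115.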

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

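The splits of the libraries and the test of low complexity for cholesterol synthesis genes were planned before their values were seen, while both tests with the clock score and the other tests of the count between the male groups and of the count in tumours were chosen after the result was seen.

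The effect of the knockout differed between females and males by the test of the difference itself. This holds for 1945 genes, for 23 members of cholesterol synthesis and for 16 of the 38 lists with the preset correlation, of which 0 passed with an estimated correlation. Between the sexes 4137 genes passed in wild type and 70 in knockout liver (non-tumour in females). The mean log2 CPM of cholesterol synthesis was 3.225 in wild-type males, against 5.083 to 6.562 in the other groups. Where the difference rests on the wild-type males, it cannot be told apart from the features in which their libraries stood apart. Among named genes the adjusted p of the difference was 0.00216 for Pdgfrl, 0.00519 for Mmp7, 0.003 for Elovl3, 0.0183 for Tuba8 and 0.02 for Cdkn1a, all with the higher female than male effect. It was 0.00561 for Ptgds, 0.000157 for Cyp3a16, 0.000157 for Cyp2g1, 0.00137 for Ptp4a1 and 0.0201 for R3hdml, with the lower female effect. The 1945 genes became 576 without wild-type female 3, 884 without non-tumour 1, 1016 without wild-type female 2, 1228 without knockout male 1 and 421 with the clock score as a covariate. Tuba8, Cdkn1a and R3hdml lost the call without either wild-type female, and Ptgds without wild-type female 3.

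More genes passed between knockout and wild-type males (3688) than between non-tumour knockout and wild-type females (743), and the wild-type male libraries hold fewer weakly counted genes than all others. Loss of weakly counted genes in these libraries as the whole cause is argued against by genes with a mean over 64 CPM. Of these, 31.9% passed in males and 10.4% in females. This does not cover other features of the wild-type male libraries, such as their rRNA share, and the female share rests on 2 wild-type libraries. Under 1 CPM the ratio of rising to falling calls was 8.26, against 2.97 over 64 CPM, so low complexity may account for part of the weakly expressed calls. The phase of the daily clock stays open: with the clock score as a covariate the median size of the log2 fold changes of the called genes went from 1.53 to 1.19 while the median SE went from 0.345 to 0.527, so the 278 remaining calls reflect both a smaller fold and a wider error, and the score parts the male groups without overlap. The hours of sampling are not used here, and a larger knockout effect in males remains as an open biological explanation.

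Cholesterol synthesis genes rose in knockout males, with the lowest levels in wild-type males. Genes of like expression level did not rise as much, since the median of the list lay at percentile 100 of 10000 random lists matched on expression. The list was taken up because 23 of its 24 members rose in these same data. A high percentile was therefore likely in advance and is no independent evidence against low complexity. The random lists held genes drawn singly, while genes of 1 pathway can move together. The percentile therefore does not speak on other features of the wild-type male libraries. With the clock score as a covariate the median went from 2.94 to 1.44, the median SE of the single members from 0.468 to 0.602, and the members past the threshold from 23 to 6. The value of 1.44 met the limit for clock phase written down before it was seen, 0.5 of 2.94. A demand that it be met by more than the median SE of the members was added after the value was seen, and was not met. That SE belongs to single genes and not to the median of the list, so this demand decides nothing. Clock phase therefore stays a candidate explanation beside the knockout, and the groups do not allow the 2 to be told apart.

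Few genes passed between tumour and non-tumour tissue. With the number as a block, which may or may not stand for the animal, 2 genes passed. This leaves open whether differences between animals hide more. With the block and both libraries of number 1 left out 46 passed, against 0 without number 2 and 0 without number 3. Genes over 2-fold apart between the tissues numbered 119 in number 1, 539 in number 2 and 943 in number 3, and number 1 was picked to be left out after this was seen, so the 46 genes decide nothing about the cause of the low count. Number 1 also stood apart in the clock score, at −0.597 in tumour and −1.04 in non-tumour tissue, against 2.16 to 4.48 in numbers 2 and 3. Tumour 1 held 3676 genes with 1 to 9 counts, against 5170 and 5224 in tumours 2 and 3. With the clock score as a covariate 0 genes passed between the tissues. Whether such features, or the state of the tumour in each animal, lie behind the low count was not tested.

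Other splits of the same libraries were counted, and in each case the splits were too few for a share under 0.05. Each other split also mixes the real groups. Where these differ widely, the mixing widens the spread, so few calls were likely in advance and a low count decides nothing. Between knockout and wild-type males the real split gave 3688 genes, and the highest of the others 0 (1 of 10 splits gave as many). Between knockout males and non-tumour females the real split gave 70 and the highest other 0 (1 of 10). Between tumour and non-tumour tissue the real split gave 0, so 10 of 10 gave as many, and the highest other gave 33, for tumour 1, non-tumour 1 and non-tumour 3 against the rest, which may point to a structure of the samples beside the tissue, picked as the highest and not tested. Among the 4 splits that part all 3 pairs, with the block, the real one gave 2 and the highest other 1 (1 of 4).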

How the results depend on the processing

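The clock score covariate and the settings without number 1 were chosen after the result was seen. Genes past the threshold are given in the order of the comparisons in the methods; the cause was not tested for any shift. Without a low-count filter 1739 genes passed between non-tumour knockout and wild-type females (743 reported), 338 between tumour and non-tumour (0 reported) and 700 between knockout males and females (70 reported). DESeq2 gave 1942, 29 and 470 for these 3, 3030 for tumour against wild type (1718 reported) and 3039 for the difference between the sexes (1945 reported). Limma-voom gave 3397, 0 and 710 for the same 3, 4599 for tumour against wild type and 3333 for the difference between the sexes. The compared groups alone gave 2262 between the male groups (3688 reported), 1824 between wild-type males and females (4137 reported) and 115 between knockout males and females. The block gave 93, 2 and 1083 in the 3 comparisons within females, and changed no other call of a count. No pairing was read outside tumour and non-tumour, so a crossed pairing does not apply.

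The clock score covariate gave 278 between the male groups, 421 for the difference between the sexes and 1801 between wild-type males and females. Both libraries of number 1 left out gave 235 between non-tumour knockout and wild-type females, 20 between tumour and non-tumour (46 with the block) and 990 for the difference between the sexes. RLE scaling, upper-quartile scaling and 1 CPM in 3 libraries left these counts within 1.5 times. Of the list calls 108 passed with the preset correlation, 105 with RLE and 106 with upper-quartile scaling, and 3 with an estimated correlation.

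Leaving out each library in turn gave 17 to 921 for non-tumour knockout against wild-type females, 0 to 42 for tumour against non-tumour, 157 to 1378 for tumour against wild type, 2462 to 4055 for the male groups, 576 to 2604 for the difference between the sexes, 1290 to 4775 for wild-type males against females and 19 to 143 for knockout males against females. With 1 wild-type female left, its spread is assumed to be that of the other groups.

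Of 478 pairs of a named gene and a comparison, the call held in 474 with DESeq2, 421 with limma-voom, 391 with the groups alone, 351 with the block and 292 with the clock score. Only Serpina1e between the male groups changed sign, from −4.42 to 0.0451 with the clock score. Genes shared in the same direction by the female and male effects numbered 206, with 221 at 1 CPM in 3 libraries and 191 with the groups alone, and Pearson's r was −0.0291, 0.0598 and 0.0851.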

Other observations

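No test in this part was chosen after the result was seen. In tumours against wild-type females, genes of glycolysis rose in 3 of 17 cases, among them Gpi1, glucose-6-phosphate isomerase (2.27 ± 0.36, edgeR adjusted p = 0.00212), and Pfkl, liver phosphofructokinase (0.92 ± 0.23, edgeR adjusted p = 0.0244). Adjusted over the list alone 4 rose, with adjusted p = 0.327 with an estimated correlation. The count of 3 went to 0 without wild-type female 3. In non-tumour knockout against wild-type females, all 26 genes of the mitochondrial respiratory chain had a positive log2 fold change (median 0.99) and 0 passed edgeR's test over all genes. Of these 15 were higher adjusted over the list alone, with adjusted p = 0.479 with an estimated correlation. The 9 mitochondrially encoded genes all had a negative one (median −0.57; 2 lower adjusted over the list alone), and the mitochondrial share of counts was 19.1, 34.2 and 16.7% in non-tumour 1, 2 and 3 against 34.6 and 33.3% in wild-type females 2 and 3. Whether library quality moved the respiratory chain list was not tested. In knockout males against non-tumour females, Ctgf (−2.01 ± 0.37), a matricellular protein gene, and Timp2 (−1.63 ± 0.31), a metalloproteinase inhibitor, of the fibrosis and stellate cell list were lower, 2 adjusted over the list alone (adjusted p = 0.238 with an estimated correlation). These lists were fixed in advance.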
